A study of Mus musculus with 2 samples.

How the data were processed

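H3K36me3 ChIP-seq libraries from pooled kidneys of mouse embryos at embryonic day 15.5 were analysed as 1 group of 2 biological replicates. Per the labels, replicate 1 was a pool of 78 embryos with 2 technical replicates and replicate 2 a pool of 62 embryos with 3 technical replicates, both of strain B6NCrl and of mixed sex. The pools were of separate embryos, and technical replicates were already combined within each peak list. Control libraries named in the labels were not analysed here. The design holds no comparison between conditions.

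The authors deposited 4 peak lists in narrowPeak format on the mm10 assembly, per the accompanying README. There was 1 list for each replicate, 1 called on the pooled reads of both replicates, and 1 of replicated peaks derived from the pooled list and both replicate lists. Per the README, the replicate 1 list was derived from its alignment and 2 further files, and the replicate 2 list from its alignment and 1 further file. What the further files hold, such as control alignments, is not stated. The aligner, the peak caller and their versions are not given in the sources used here. In each of the authors' lists the seventh column holds a ratio, the enrichment of the peak as the peak caller wrote it, whose definition is not stated. The ninth column of the deposited lists holds −log10 of the q-value of each peak. Its lowest value was 0.708 in replicate 1, so the lists include weak peaks. Because the lists give positions and scores without read counts, depth is unknown, no interval or floor that needs it is given, and library depth and calling threshold can both change the number and width of peaks. A replicate with deeper reads can yield wider or more peaks with no difference in the mark. Broad H3K36me3 domains are split into short peaks in this format, so coverage of genes and joined domains are reported beside peak counts. A gene without peaks can still carry the mark under the calling threshold.

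Peaks on chromosomes 1 to 19, X and Y were used. Peaks on unplaced or unlocalised scaffolds (19 in replicate 1, 19 in replicate 2, 23 pooled and 10 replicated) were left out of the comparisons. All coordinates are mm10, printed from 1. Gene models were GENCODE protein-coding genes on the matching GRCm38 assembly, 21938 in all, and peaks lay within its chromosome lengths. For each gene the percent of the body (start to end of the gene) covered by peaks was computed, and a gene with at least 10% covered by replicated peaks was called marked. Of these genes 4754 overlapped another protein-coding gene, and a peak in shared sequence was counted for each. Bases were assigned to exon, then intron, then promoter (1 kb upstream of the start), then intergenic sequence. Domains were made by joining replicated peaks within 3 kb.

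The overlap of peaks counted as shared was at least 50% of the peak. Background came from 100 placements of the same peaks at random within their chromosome outside assembly gaps, which do not model mappability. Differences between parts of genes were tested by sign-flip permutation over genes (100000 resamples, two-sided). The X chromosome was compared with genes of the same length decile by 100000 permutation draws. Gene lists (26) and families taken by symbol (8) were tested against 10000 random lists matched on decile of gene length (two-sided), with Benjamini-Hochberg adjustment over the 34. These p-values are over genes of 1 tissue and not over replicates. Of 344 list genes 343 were found in the annotation, and Ahsp of the erythroid list was not. H13, the Rps6k kinases and Rps19bp1, which symbol patterns also took, were removed from the families as not being members.

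Gene lists, tests, thresholds and the rule for named genes were fixed before the data were examined. The rule took, of each list, up to 4 marked genes with the highest covered share and up to 3 unmarked genes in list order. It also took the 20 genes of at least 10 kb with the highest covered share, the 10 genes of at least 5 kb with the largest difference between replicates, the 5 widest domains and the 5 replicated peaks with the highest enrichment. Neighbouring genes named as sharing a domain with a marker were looked up after the marker's value was seen, and the shares of marked genes in such domains were counted later still. Alternatives were an overlap of 1 bp or reciprocal 50%, peaks with −log10 q of at least 3, equal numbers of top peaks, marking at 5% or 20%, each replicate alone, the pooled list, genes of at least 20 kb, a 2 kb promoter and joining within 1 kb or 10 kb. Genes that overlap no other gene, the distal part of the gene body and internal exons were added after the data were seen.

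Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The code was tested on simulated data. Of 150 genes with at least 20% of the body planted with peaks all 150 were found marked, as were 16 of 50 planted at 5%, where other random peaks added to them. Random peaks marked 3417 of 21738 other genes. Coverage equalled that of bedtools 2.31.1 in 2000 of 2000 genes. With genes marked at random at the real share of each length decile, random lists of 15 genes had p under 0.05 in 12 of 400 cases, and lists of 12 marked and 3 unmarked genes in 100 of 100. The sign-flip test gave p under 0.05 in 7 of 200 samples with no effect.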

Results

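Trimethylation of histone H3 at lysine 36 (H3K36me3), a mark laid down over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the kidneys of mouse embryos at embryonic day 15.5. The kidney at this stage holds nephron progenitors of the cap mesenchyme, the branching ureteric bud, the first nephrons and stroma. All libraries formed 1 group of 2 biological replicates from separate pools of male and female embryos of strain B6NCrl. Replicate 1 came from 78 embryos and replicate 2 from 62 embryos. With no other tissue, stage or control library analysed here, the comparisons were between the replicates, between peaks and randomly placed peaks, and between gene groups within the tissue. The authors' peaks numbered 187277 in replicate 1 and 173647 in replicate 2, and covered 119.7 Mb and 128.9 Mb of the mm10 genome. Their pooled list, called on the reads of both replicates, held 178872 peaks, and their replicated list held 121711 peaks that covered 139.6 Mb, or 5.27% of the sequenced bases of the chromosomes. Peak lists hold no read counts, so the depth of each library is unknown. Peaks of the replicated list had a median width of 660 bp and a median enrichment of 3.32, a value given by the authors' peak caller that is used here to rank and compare peaks within a list.

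The replicates marked largely the same sequence. They shared 96.7 Mb, which was 80.8% of the bases covered in replicate 1 and 75% of those covered in replicate 2, and the Jaccard index (shared over combined bases) was 0.637 against 0.0272 for randomly placed peaks. Of the replicate 1 peaks, 67.3% were overlapped over at least 50% of their width by a replicate 2 peak, against 4.96% on random placement. Of the replicate 2 peaks, 57.3% were overlapped by a replicate 1 peak, against 4.39% on random placement. Each of these values exceeded all 100 random placements (one-sided permutation p = 0.0099, the smallest possible with 100 placements). Weak peaks were shared less often. In the lowest decile of enrichment 41.1% of replicate 1 peaks and 40.4% of replicate 2 peaks were shared, and in the highest decile 96.5% and 85.0% were shared. All 121711 replicated peaks had the same coordinates as a pooled peak and made up 68.0% of the pooled list. Peaks of both replicates overlapped at least 50% of the width of 53.1% of them and at least 1 bp of 85.0%. When 50% of either the pooled or the replicate's peak was enough, 84.4% were overlapped in both replicates. Of the 57148 pooled peaks left out of the replicated list, 0 met this. Pooled peaks outside the replicated list were narrower, with a median width of 237 bp.

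H3K36me3 lay in gene bodies and was sparse at their starts. Introns of protein-coding genes held 72.4% of the bases covered by replicated peaks, against 38.0% on random placement, and exons held 22.2%, against 3.99%. The 1 kb upstream of transcription starts held 0.0715%, against 0.739% on random placement, and sequence outside genes and promoters held 5.27%, against 57.3%. All 4 shares lay beyond every random placement (two-sided permutation p = 0.02, the smallest possible with 100 placements). Exons held 22.8% of the covered bases of replicate 1 alone and 22.6% of those of replicate 2 alone. Within genes of at least 5 kb, the mean covered share rose from 1.5% in the first of 20 bins to 32.5% in bin 19, and fell to 12.9% in the fifth kilobase downstream of the gene end. The last part of the body, divided in 3, had a mean covered share of 30.5%, against 11.5% in the first part. This difference of 18.95 percentage points (SD 30.0 over 17798 genes) had a sign-flip permutation p = 1e-05, the smallest that 100000 resamples give. The last part was the more covered in 8598 genes and the first part in 1262. In marked genes, defined below by a covered share of at least 10%, exons were more covered than introns, at 61.7% against 45.0%. That difference of 16.7 percentage points (SD 25.4 over 8663 genes) also had a permutation p = 1e-05. Exonic and intronic bases were not matched on position, so this difference is not told apart from the rise toward gene ends. Genes are not independent replicates, and these p-values describe the spread over genes of 1 tissue.

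**Figure D1:**
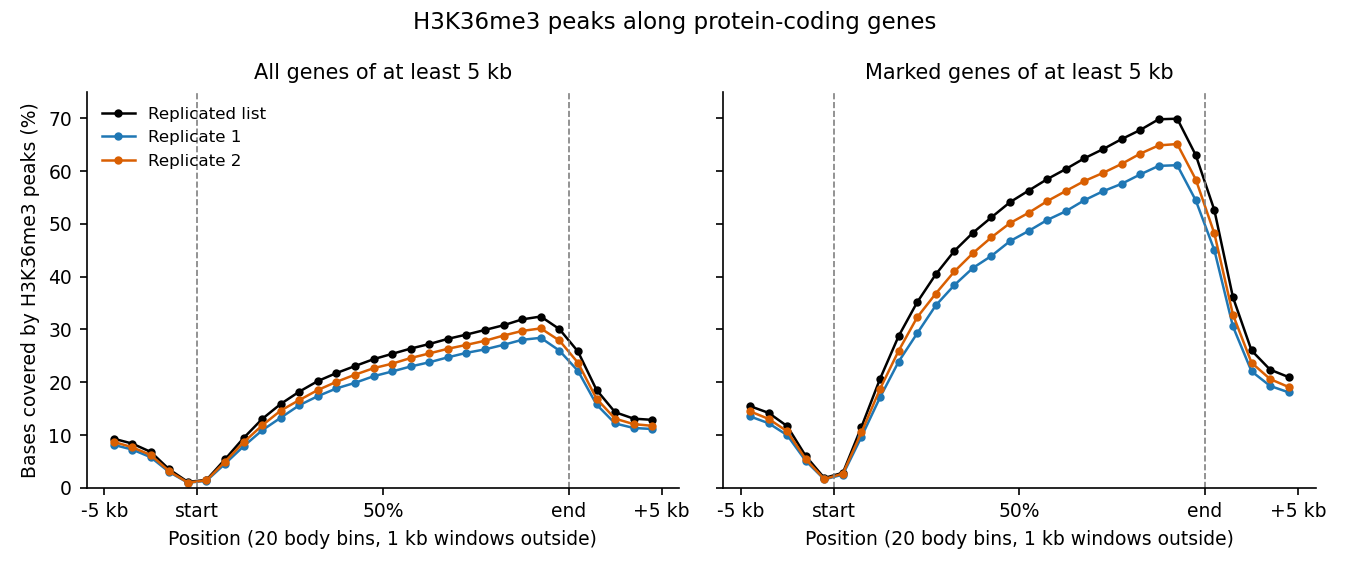
Mean percent of bases covered by H3K36me3 peaks (y axis) in 20 bins from start to end of protein-coding genes of at least 5 kb and in 1 kb windows up to 5 kb outside them (x axis), for all such genes (left) and marked genes (right). Lines stand for the replicated list and for each replicate; coverage in the replicated list is lowest in the 1 kb window upstream of the start (1.12% over all genes and 1.86% over marked genes), reaches 32.5% over all genes and 69.9% over marked genes in bin 19 of the replicated list, and is higher in replicate 2 than in replicate 1.

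At least 10% of the body was covered in 8792 of 21938 protein-coding genes (40.1%), which are called marked here. Randomly placed peaks marked 3448 genes (SD 55 over 100 placements). The median marked gene was covered over 48.7% of its body, and 10988 genes held no replicated peak. Among the genes of at least 10 kb with the highest covered share, Trrap, a scaffold of histone acetyltransferase complexes (chromosome 5, 144767732 to 144859778), was covered over 96.2% of its 92.1 kb. The splicing factor genes Sf3a1, Snrnp70, Sf3a3, Sf3b3, Prpf8 and Snrnp200 were covered over 96.1%, 94.2%, 93.8%, 93.5%, 93.5% and 93.1%. Rnf40, an E3 ligase for histone H2B, was covered over 94.9%, the nuclear import gene Kpnb1 over 93.7%, the glycolytic gene Gpi1 over 93.6%, the chromatin remodeller Chd4 over 92.9%, the condensin gene Ncapd2 over 92.9% and the topoisomerase gene Top2a over 92.7%. Among the 20 highest, these genes had replicate values between 87.0% and 95.5%. The remaining genes of those 20 were 1700109H08Rik, Phykpl, Gm42715, Prr12, Srp68, Copg1 and Pdcd11, at 92.6% to 95.2%.

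Between the replicates, the covered share had a Pearson r of 0.989 and a Spearman rho of 0.976 across the 21938 genes, which are not independent replicates and many of which hold no peak. It differed by at least 10 percentage points in 875 genes. Replicate 1 marked 8554 genes and replicate 2 marked 8627. Both marked 8341, or 94.4% of the genes marked in either, while 213 were marked in replicate 1 alone and 286 in replicate 2 alone. Coverage was on average 1.17 percentage points higher in replicate 2 (SD 4.04), with 8092 genes higher in replicate 2 and 3705 higher in replicate 1. The 10 genes of at least 5 kb that differed most were all more covered in replicate 2. They were Rbbp7, Dmac2, Serp1, Aga, Col1a1, P3h4, Suv39h1, Cln5, Ankrd61 and Acot2, with differences of 21.3 to 27.4 percentage points. Col1a1, which encodes a chain of type I collagen, was covered over 31.5% in replicate 1 and 55.0% in replicate 2. P3h4, which acts in collagen modification, was covered over 26.4% and 49.8%. Rbbp7, an X-linked histone chaperone gene, was covered over 22.9% and 50.4%.

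**Figure D2:**
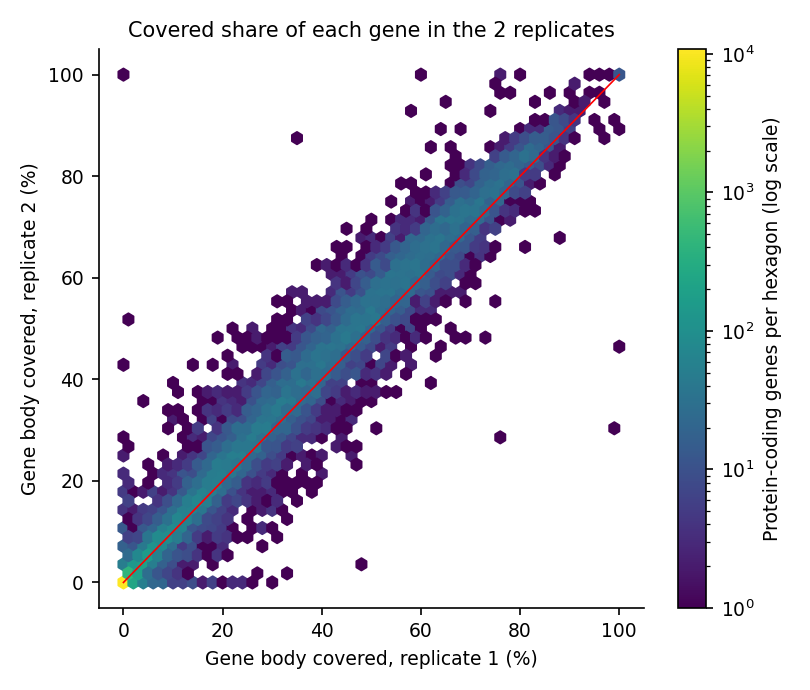
Percent of each protein-coding gene body covered by the peaks of replicate 1 (x axis) and replicate 2 (y axis), with colour giving the number of genes per hexagon on a log scale and a red line at equal values. The 21938 genes follow the line with r = 0.989, and more genes lie above it (8092) than under it (3705).

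Of the 34 lists and families, 8 were marked more often than random lists. All 20 cell cycle genes, all 20 housekeeping genes and all 19 genes of the H3K36 methylation machinery were marked, against 9.12, 8.79 and 8.71 genes in random lists matched on gene length. Of the cell cycle genes, Top2a, Aurka, Mcm2 and Mcm5 were covered over 92.7%, 91.2%, 89.0% and 88.3%. Of the methylation machinery, the demethylase gene Kdm4a was covered over 91.8%, the elongation factor gene Supt6 over 83.6%, the methyltransferase gene Nsd1 over 80.3% and Psip1, whose product binds the mark, over 79.4%. The housekeeping genes Eef2 and Hsp90ab1 were covered over 84.5% and 82.3%. Ribosomal protein genes (72 of 81), mitochondrial complex I subunits (41 of 46) and proteasome subunits (33 of 40) were also marked more often than the 20.7, 17.0 and 17.3 genes of matched random lists. Zinc finger genes with Zfp symbols were marked in 289 of 394 cases, against 183.3 in random lists. Of collagen and matrix genes 16 of 18 were marked, against 7.58. Lamb1 and Fn1, which encode laminin and fibronectin chains, were covered over 89.4% and 88.2%, while Col5a2 at 2.66% and Col6a3 at 7.93% were not marked. Each of these 8 groups had an adjusted permutation p of 0.00068 (two-sided, 10000 random lists, Benjamini-Hochberg over 34 lists and families), and each kept p under the threshold in all 9 settings.

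Genes of the kidney's own lineages were marked in part, and the counts of those lists did not differ from random lists. In the nephron progenitor list 5 of 16 genes were marked, against 6.31 in random lists (adjusted permutation p = 0.70). Pax2 and Wt1, transcription factor genes required for kidney formation, were covered over 65.2% of 81.8 kb (chromosome 19, 44756045 to 44837871) and 53.3% of 47.1 kb (chromosome 2, 105126529 to 105173616). Sall1 was covered over 34.1%, and Gdnf, the growth factor that induces the ureteric bud, over 23.6%. These shares are of the replicated list, and those of each replicate can be lower, as for Pax2 at 49.5% and 57.5%. Six2, which maintains nephron progenitors (chromosome 17, 85684277 to 85688274, 4.00 kb), held no peak in the replicated list or in either replicate. Cited1 held none in the replicated list, and Eya1 was covered over 1.12%. In the ureteric bud and collecting duct list 5 of 18 were marked, against 7.86 (adjusted permutation p = 0.29). Hnf1b was covered over 50.7%, the Ret target genes Spry1, Etv5 and Etv4 over 42.5%, 36.4% and 14.4%, and Ret itself, the GDNF receptor gene (46.0 kb), over 0%. Wnt9b and Wnt7b also held no replicated peak. Etv4 passed 10% in replicate 1 (13.9%) and not in replicate 2 (7.91%). In the early nephron list 6 of 15 were marked, against 5.46 (adjusted permutation p = 0.96). Ccnd1, Jag1, Notch2 and Pax8 were covered over 72.2%, 59.5%, 49.6% and 40.4%, and Wnt4 at 8.81%, Lhx1 and Fgf8, both at 0%, were not marked. Wnt4 was at 6.86% in replicate 1 and 12.3% in replicate 2. In the stroma list 10 of 16 were marked, against 6.40 (adjusted permutation p = 0.14). Col1a1, Pdgfra, Pdgfrb and Meis2 were covered over 63.9%, 52.0%, 40.8% and 34.7%, and Foxd1, a transcription factor gene of stromal progenitors, held no peak. The Hox paralog genes 9 to 11 were marked in 0 of 10 cases, against 3.16 (adjusted permutation p = 0.059, and 0.048 on the pooled list), and those of groups 12 and 13 in 0 of 6, against 1.49 (adjusted permutation p = 0.37).

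Genes of differentiated nephron segments were rarely marked. In the proximal tubule list 1 of 16 genes was marked, against 6.84 in random lists (adjusted permutation p = 0.011). That gene was Slc5a2, a glucose transporter gene covered over 23.5%, which overlaps another gene, and its peaks formed part of a 25.4 kb domain with BC017158. Hnf4a and Slc34a1 held no replicated peak, and the endocytic receptor gene Lrp2 was covered over 1.99%. In the loop of Henle and distal tubule list 1 of 12 was marked, the kinase gene Wnk1 at 38.5%, partly in a 67.9 kb domain with Rad52, against 5.41 (adjusted permutation p = 0.026). Umod, Slc12a1 and Slc12a3 were at 0%. The loop call was lost with marking at 20% coverage (adjusted permutation p = 0.078) and with genes that overlap no other (0.056). In the podocyte list 1 of 15 was marked, the growth factor gene Vegfa at 61.0%, against 5.22 (adjusted permutation p = 0.041), and the slit diaphragm genes Nphs1 and Nphs2 and the transcription factor gene Mafb were at 0%. The podocyte call was lost without replicate 1 (adjusted permutation p = 0.051), with marking at 20% (0.11) and with genes that overlap no other (0.11). Of adult kidney solute carriers 1 of 10 was marked, Slc5a2 again, against 4.42 (adjusted permutation p = 0.073). That list passed the threshold with marking at 5% (0.042) and on the pooled list (0.046).

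Markers of nerve, muscle, liver and eye were not marked. This held for 0 of 13 nerve and chromaffin genes such as Phox2b and Th (adjusted permutation p = 0.0034), 0 of 12 neuronal genes such as Syt1 and Snap25 (0.0073), 0 of 12 liver genes such as Alb and Ttr (0.0073) and 0 of 12 skeletal muscle genes such as Ckm (0.02). It also held for 0 of 10 cardiac genes such as Myh6 (adjusted permutation p = 0.026) and 0 of 10 photoreceptor and lens genes such as Rho (0.024). The cardiac call was lost with marking at 20% (adjusted permutation p = 0.063) and with genes that overlap no other (0.11). The photoreceptor and lens call was lost with marking at 5% (adjusted permutation p = 0.098) or 20% (0.072), with genes that overlap no other (0.069) and over the distal part of the body (0.14). Olfactory receptors (0 of 1135), vomeronasal receptors (0 of 329) and keratin-associated proteins (0 of 57) were unmarked as well, with adjusted permutation p-values of 0.00068, 0.00068 and 0.0037. Clustered histone genes, which are not markers of a tissue, were also unmarked (0 of 67, adjusted permutation p = 0.0012), unlike the cell cycle genes. The keratin-associated call was lost with genes that overlap no other (adjusted permutation p = 0.059).

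Blood, vessel and gonad genes were marked in few cases. Of the 7 marked genes of the erythroid, macrophage, endothelial and adrenal and gonad lists, 6 lay in a domain of joined peaks that another gene overlaps, as did 3589 of all 8792 marked genes (40.8%) and 2 of 26 in the nephron progenitor, ureteric, early nephron and stroma lists. In the erythroid list 1 of 10 genes was marked, against 4.75 in random lists (adjusted permutation p = 0.044), and Gypa and Klf1 held no peak. The marked gene was Epor, the erythropoietin receptor gene, at 21.5%, with 9.22% in replicate 1 and 11.6% in replicate 2, in a 1.83 kb domain with Swsap1. The erythroid call was lost without replicate 1 (adjusted permutation p = 0.19), with marking at 5% (0.14) or 20% (0.094), on the pooled list (0.15) and with genes that overlap no other (0.15). In the macrophage and leukocyte list 2 of 12 were marked, against 4.28 (adjusted permutation p = 0.29), while Ptprc and Adgre1 held no peak. Cd68, 1.94 kb long, was covered over 100%, inside a 44.5 kb domain on chromosome 11 with Fxr2, Sox15, Mpdu1, Eif4a1 and Senp3. Cx3cr1 was covered over 20.7%, in domains with Wdr48, Gorasp1 and Csrnp1. In the endothelial list 2 of 13 were marked, against 5.04 (adjusted permutation p = 0.15, and 0.026 with marking at 20%), Eng at 19.3%, in a domain with Fpgs, and Ets1 at 16.7%, in a domain of its own, while Pecam1 and Cdh5 held no replicated peak. In the adrenal cortex and gonad list 2 of 11 were marked, against 4.42 (adjusted permutation p = 0.27). They were Star, at 54.1% in a 28.8 kb domain with Ash2l, and Amh, at 17.7% in a 5.12 kb domain with Sf3a2. In the spermatid list 1 of 11 was marked, against 3.23 (adjusted permutation p = 0.27), and Prm1, Prm2 and Tnp1 held no peak. The marked gene was Gapdhs, at 40.0% in a 7.93 kb domain of its own. The spermatid list was not in the count of 7 marked genes above, which was made after the domains were seen. Of imprinted genes 9 of 17 were marked, against 6.59 (adjusted permutation p = 0.34). Nnat, Igf2r, Peg3 and Grb10 were covered over 91.5%, 73.4%, 71.5% and 47.9%, Nnat inside a domain with Blcap, and Dlk1 and Cdkn1c held no replicated peak.

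**Figure D3:**
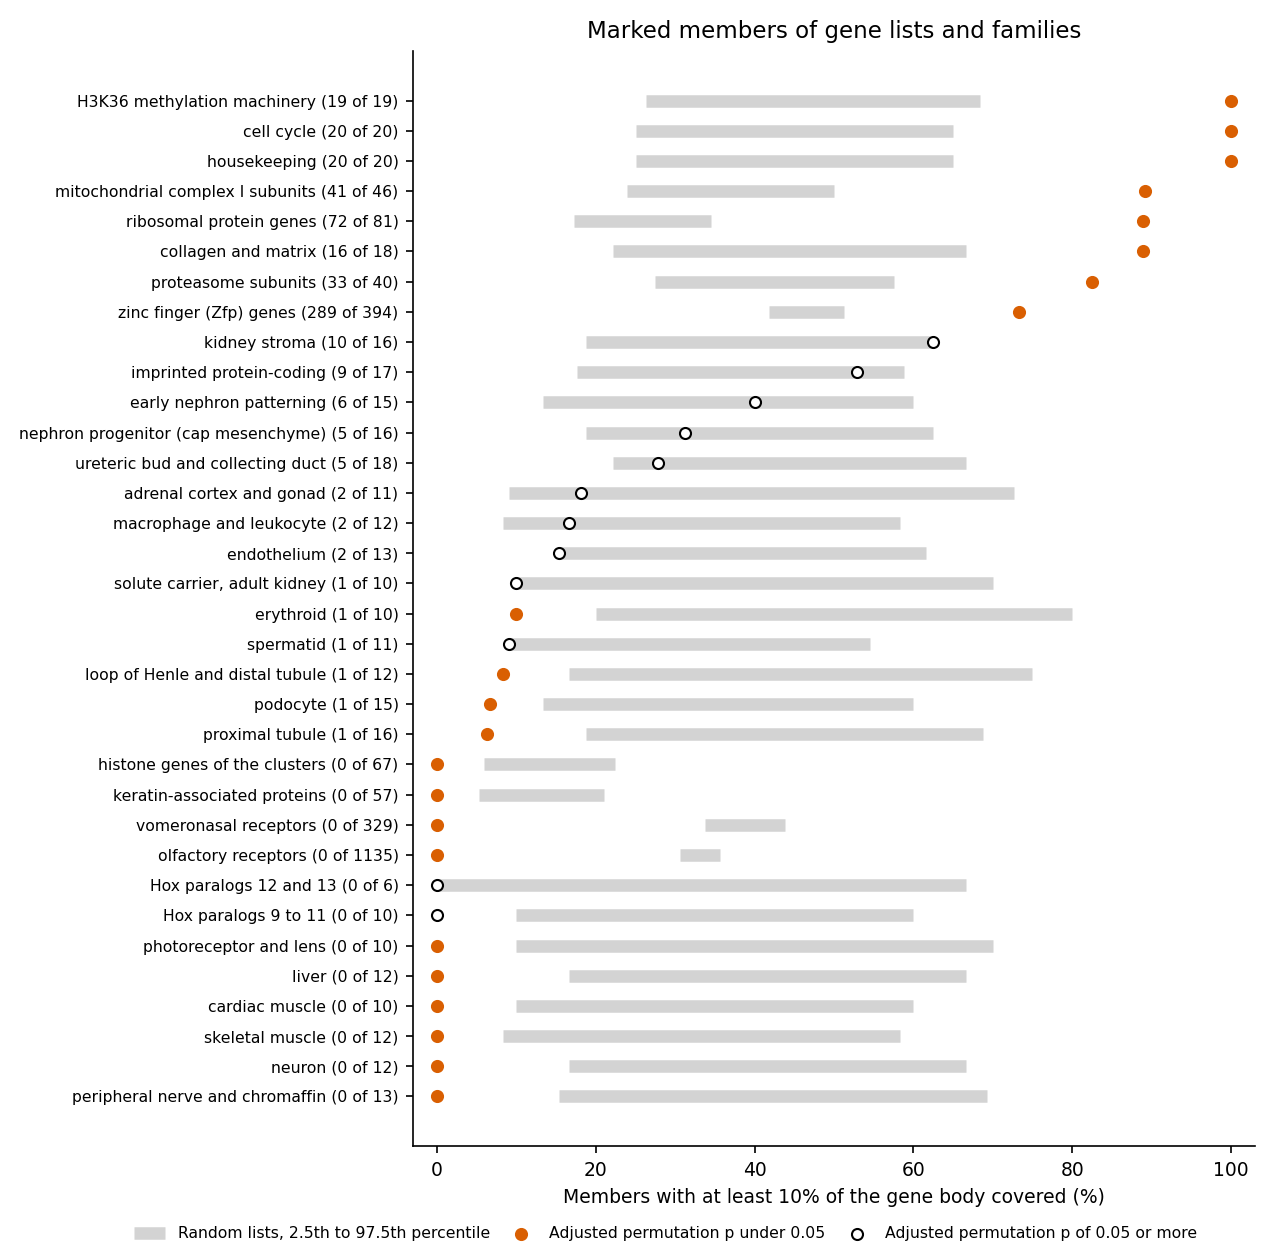
Percent of the members of each gene list or family with at least 10% of the body covered by replicated H3K36me3 peaks (x axis), with counts beside the names, and grey bars for the range of 95% of random lists matched on gene length. Filled points have an adjusted permutation p under 0.05, 8 lists to the right of their bars and 14 to the left; open points do not.

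The X chromosome was marked less than the autosomes. Of its 948 protein-coding genes 15.9% were marked, against 41.5% of autosomal genes and 36.6% expected for genes of the same lengths (two-sided permutation p = 2e-05, the smallest that 100000 draws give). Replicated peaks covered 9.53 kb per Mb of the X chromosome, and between 37.5 kb per Mb on chromosome 3 and 94.9 kb per Mb on chromosome 11 among autosomes. The X value was 7.41 kb per Mb in replicate 1 and 9.49 kb per Mb in replicate 2. On the Y chromosome 0 of 183 genes were marked, and it held 13 replicated peaks. Mappability was not modelled, so a lack of called peaks on the X or Y chromosome is not shown to be a lack of the mark. Replicated X peaks had a median enrichment of 2.99, against 3.15 for autosomal peaks of the same widths. The pools were of both sexes.

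**Figure D4:**
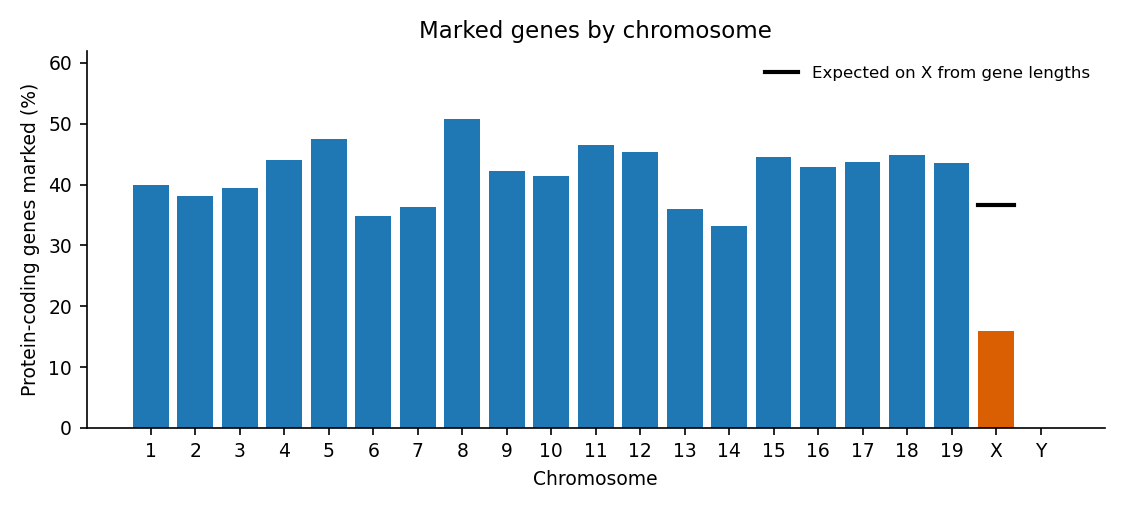
Percent of protein-coding genes with at least 10% of the body covered by replicated H3K36me3 peaks (y axis) on each chromosome (x axis). The autosomes lie between 33.2% (chromosome 14) and 50.8% (chromosome 8), the X chromosome at 15.9% lies under the black line at 36.6% expected from its gene lengths, and the Y chromosome is at 0%.

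Joining replicated peaks within 3 kb gave 21520 domains with a median width of 3.403 kb, of which 2960 were at least 20 kb wide, and 94.8% of their bases lay in protein-coding genes. The widest was 152.7 kb on chromosome 2 (18067106 to 18219821), over Mllt10 and Dnajc1. The next were 151.6 kb over Usp34 and Ahsa2 on chromosome 11, 148.0 kb over Adamts9 on chromosome 6, 142.7 kb within Eif4g3 on chromosome 4 and 140.1 kb within Helz on chromosome 11. The number of domains depended on the joining distance, with 37347 at 1 kb and 11524 at 10 kb. Of the 5 replicated peaks with the highest enrichment, 4 lay in zinc finger genes with Zfp symbols. The peak with the highest value, 18.4, lay in Zfp146 on chromosome 7 (30160622 to 30164448), with 2007 of its 3827 bp exonic. The next overlapped Zfp865, Zfp784 and Ccdc106 on chromosome 7 (5027393 to 5036684, enrichment 17.6), Zfp68 on chromosome 5 (138610270 to 138612280, 16.6), Zfp157 on chromosome 5 (138454328 to 138459822, 16.3) and 2610008E11Rik on chromosome 10 (79064076 to 79068113, 16.2).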

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

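Both results here were chosen after the data were seen. Outside the chromosomes that the comparisons use, 10 replicated peaks lay on unplaced or unlocalised scaffolds, where the replicate 1, replicate 2 and pooled lists held 19, 19 and 23. They are named because no comparison used them, and no expected number was computed for them. The one with the highest enrichment, 13.3, spanned 5578 bp of a scaffold assigned to chromosome 4, and 5 of the 10 lay on a scaffold assigned to the X chromosome.

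A small share of long non-coding RNA genes, which the comparisons do not use, were marked: 120 of the 6028 that lie apart from protein-coding genes (1.99%). Of 4472 such genes at least 10 kb from any protein-coding gene, 35 (0.783%) had at least 10% of the body covered by replicated peaks. No random expectation was computed for these genes. Snhg17, a small nucleolar RNA host gene on chromosome 2 (158353700 to 158361580), was covered over 85.1%, 81.6% in replicate 1 and 79.1% in replicate 2. Malat1 on chromosome 19 (5795690 to 5802672), an abundant nuclear RNA gene, was covered over 46.6%, and the X-linked Firre over 16.6% of 79.6 kb. AI506816 on chromosome 5 was covered over 44.0% and holds the ninth strongest replicated peak (23703552 to 23704887, enrichment 14.7), which lies in no protein-coding gene.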

How the results depend on the processing

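The genes that overlap no other gene, the distal part of the gene body and internal exons were settings chosen after the data were seen. Peak overlap, location, position along genes, exons against introns, the count of marked genes and the low X share kept their direction and their side of the threshold in every setting run for them, replicates left out included, and no result reversed. Marked genes numbered 7567 to 9559 of 21938 over the settings that use all genes and 6101 of 17184 (35.5%) among genes that overlap no other, the difference between last and first parts of genes was 16.4 to 18.95 percentage points, and the X share was 11.5% to 20.5%. Requiring reciprocal 50% overlap lowered the shared part of replicate 1 peaks from 67.3% to 41.6% and of replicate 2 peaks from 57.3% to 44.8%. The share of replicated peaks overlapped in both replicates rose from 53.1% to 84.96% when 1 bp was enough. Joining peaks within 1 kb gave 37347 domains and within 10 kb 11524, against 21520 within 3 kb, as the joining distance itself sets. Lists and families marked more often than random lists numbered 8 in all 9 settings. Those marked less often numbered 14 in the main setting, 13 with marking at 5%, 10 with marking at 20% and 15 on the pooled list. They numbered 8 among genes that overlap no other gene, where lists hold fewer members. Whether that alone was the cause of the 8 was not tested. Leaving out replicate 1 gave 12 lower lists and leaving out replicate 2 gave 14. Depth is unknown, so a gene at 0% is a gene without a called peak, and a mark present in a minority of cells can stay under the authors' threshold.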

Other observations

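The gene families, named RNA genes and pattern tests described here were chosen after the data were seen, and the tests of stromal against epithelial genes, of X-linked genes by the share marked and of GC content between the replicates after their results could be read from values already seen. Of 13 further families taken by symbol, 3 were marked more often than length-matched random lists, 6 less often and 4 did not pass (permutation, Benjamini-Hochberg over the 13). Spliceosome genes were marked in 39 of 41 cases (adjusted permutation p = 0.00087), ubiquitin-conjugating enzymes in 27 of 37 (0.0021) and kinesins in 25 of 39 (0.027). Wnt ligand genes were marked in 3 of 19 cases (adjusted permutation p = 0.017) and Fgf ligand genes in 1 of 22 (0.0021), both less often than random lists. The marked Wnt genes were Wnt2b at 39.6%, Wnt5a at 26.4% and Wnt11 at 12.1%, and the marked Fgf gene was Fgf22 at 74.6%. Claudins (4 of 33, adjusted permutation p = 0.016), solute carriers (128 of 338, 0.0022), cytochrome P450 genes (3 of 99, 0.00087) and defensins (0 of 64, 0.00087) were also marked less often. Notch receptors (3 of 4), Smad genes (7 of 8), integrins (9 of 26) and clustered protocadherins (21 of 55) did not pass (adjusted permutation p of 0.48, 0.053, 0.38 and 0.38).

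Zinc finger genes, counted by Zfp symbols only, held 39 of the 100 replicated peaks with the highest enrichment (39%, Wilson 95% interval 30.0% to 48.8%). They held 121 of the top 1000, against 2.007% of all replicated peaks. Lists of 1000 peaks of the same widths held 25.9 on average and at most 44 (one-sided permutation p = 0.0005, the smallest that 2000 draws give). Peaks ranked 3, 6, 18 and 51 by enrichment all lay in Zfp68. Such peaks are not independent, so the interval and the p-value overstate the certainty. The 271 marked Zfp genes of at least 5 kb had a mean coverage of 25.8% in the first and 67.2% in the last part of the body. For 7662 other marked genes these were 25.3% and 66.4%, and the difference was not tested. Among RNA genes, Mir17hg, the host of a microRNA cluster, was covered over 90.0% and Tug1 over 67.9%, while H19, an imprinted RNA gene active in embryonic tissues, held no peak in either replicate and Meg3 was covered over 3.11%. Of 5893 replicated peaks outside protein-coding genes, 4618 (78.4%) lay within 10 kb downstream of a gene end and 291 (4.94%) within 10 kb upstream of a start only.

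Genes of developmental transcription factor families were marked less often than their length predicts. Of 179 homeobox, Sox, Fox, T-box, Pax, Gata and related genes outside the fixed lists, 12.85% were marked, against 35.8% of length-matched random lists (two-sided permutation p = 0.0002, the smallest possible), which argues against gene length as the whole cause. Random lists matched on length and GC content were marked at 43.47% (permutation p = 0.0002), which argues against GC content. The deficit was present in the 107 genes under 10 kb (7.48% against 27.8%) and in the 72 longer genes (20.8% against 47.7%). Six2, Foxd1 and Lhx1 held no peak beside Pax2 at 65.2%, so expression in a minority of cells, repression in the other cells or a weak signal under the peak threshold may each contribute, and no biological explanation was tested.

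The low share of marked X genes was set against the kind of genes that the X chromosome holds. The 7 X-linked members of the ribosomal protein, proteasome and complex I families, used in all cells, were covered over 19.04% on average (SD 19.5). Autosomal members drawn from the same families had a mean of 51.5% (two-sided permutation p = 0.0012). This argues against gene content as the whole cause of the lower coverage only if gene length plays no part. The draws were matched on family and not on length, and the 7 X-linked genes were 2.29 to 8.3 kb long. They ranged from 0% in Ndufb11 to 54.7% in Rps4x, and their mean was 12.4% in replicate 1 and 20.5% in replicate 2 (permutation p of 0.0004 and 0.0038). The share of genes marked decided less: 4 of the 7 (57.14%) were marked, against 142 of 160 autosomal members (permutation p = 0.079), with 3 in replicate 1 (0.019) and 6 in replicate 2 (1). Ndufa1, at 0% in the replicated list, was covered over 13.7% in replicate 1 and 20.3% in replicate 2. For the share of genes marked, gene content therefore stays open, with too few genes to tell. X peaks were also weaker, with a median enrichment of 2.986 against 3.15 for autosomal peaks of the same widths (one-sided permutation p = 0.0005). A lower dosage of the active X chromosome, with 1 active copy per cell in both sexes, is a candidate explanation that this leaves open, as is a lower number of X reads in male embryos, which was not tested because the lists hold no counts.

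Col1a1 and P3h4 were among the genes that differed most between the replicates, and 12 of 16 matrix genes of the fixed list that were marked in either replicate were more covered in replicate 2. So were 6669 of all 8840 genes marked in either replicate, so that count alone does not set the matrix genes apart. The 49 matrix genes outside that list differed by 3.013 percentage points (SD 4.62), against 2.54 for genes of like length and coverage (two-sided permutation p = 0.56) and 2.92 for all genes marked in either replicate, so a general difference in peak width between the replicates remains a candidate explanation. Genes of like GC content and coverage differed by 1.844 points (two-sided permutation p = 0.2), which by the criterion written before the result goes with GC content. The bound that counts against it was added after these values were seen. Across genes marked in either replicate GC content and the difference had a Pearson r of -0.25, the matrix genes had a mean GC content of 49.6% against 46.7%, and adding GC to the matching on coverage changed the expected difference by -0.696 points (bootstrap 95% interval of the change -0.795 to -0.601). This argues against GC content as a cause of the higher coverage of the matrix genes in replicate 2. It does not set GC content aside for other genes, since lower GC content went with a larger difference across genes marked in either replicate. The difference, replicate 2 minus replicate 1, was 5.94 points over 10 stroma genes and -0.277 points over 12 ureteric and early nephron genes, 6.215 points apart (two-sided permutation p = 0.018, chosen after the values were seen). Col1a1 is among those stroma genes. Without it the stroma mean was 3.99 points (SD 5.12), against 2.92 for all genes marked in either replicate, and the sets were 4.27 points apart (permutation p = 0.039). Without Col1a1 and Col3a1 they were 5.07 points apart (permutation p = 0.018), with a stroma mean of 4.79. The housekeeping list differed by 3.74 points and the cell cycle list by 3.19, near the stroma mean without Col1a1. Much of the gap thus lay in the low mean of the ureteric and early nephron genes. Unlike the matrix genes, the stroma set and the ureteric and early nephron set were not matched on length, GC content or coverage. Their p-values therefore cannot tell cell share from these. A different share of stromal cells in the 2 pools stays open, as a hypothesis found and tested on the same genes. Whether the replicates were called against different controls is not stated, so different controls could also produce differences between the replicates, which was not tested.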
